A study of Mus musculus with 16 samples.

How the data were processed

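RNA was measured in 16 sequencing libraries of E14tg2a mouse embryonic stem cells, in 8 groups of 2. The labels name 3 kinds of cells, WT, DKO and P14, and 3 stages. The first stage is 2i medium, a serum-free medium with LIF at 1000 U/mL and inhibitors of MEK (PD0325901, 1 µM) and GSK3β (CHIR99021, 3 µM) that holds cells in the naive state. The other stages are day 2 and day 4 of epiblast-like cell induction with bFGF at 12 ng/mL on fibronectin. P14 cells have no group in 2i medium. The series describes wild-type cells, cells with a knockout in cis of Prdm14, and cells overexpressing it; DKO and P14 were matched to the last 2 by elimination. Total RNA was used with a stranded Collibri library kit, per the labels' protocols.

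Reads were trimmed with Trim Galore, aligned with HISAT2 and assigned to genes with featureCounts against mm10/GRCm38, per the submitters' processing notes. The tool versions, the gene annotation, the strand setting, the treatment of reads that overlap more than 1 gene and the scaling of the libraries are not given in the sources used here. The values deposited by the authors are log2 values with 1 column per library and 1 entry per gene. Raising 2 to each deposited value and subtracting 4 gave whole multiples of 1 step per library. Under 1000 reads, 100% of the values of each library were whole within 0.1 of a read. The deposited values were therefore read as log2 of a normalized read count plus 4, with 1 scaling factor per library (steps of 0.792 to 1.26). The recovered totals were 20696359 to 32710607 reads per library. Where a group had a library without reads, the fold is given as a lower bound ("at least"), with each of its libraries at its value or at 3 reads, whichever is higher; this covers counting error of low counts only.

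The table held 22122 entries, of which 21455 carried a gene symbol; all of these were found in the GENCODE M21 annotation of GRCm38, which supplied the coordinates. The 667 entries without a symbol took 7.61% to 11.1% of a library's reads and were not tested. 3 symbols stood on more than 1 entry, and each such entry was tested separately. No column came from another series.

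Values were returned to the normalized count scale and analysed as log2(value + 1). Genes with a value of at least 1 in 2 or more libraries were kept (21450 genes). limma 3.58.1 in R 4.3.3 fitted all 16 libraries in 1 model with 8 group means and a trended variance. Within each comparison the p-values were adjusted over all genes with the Benjamini-Hochberg method, with a threshold of 0.05. They were not adjusted across comparisons. There were 11 comparisons: the 3 WT stages against each other, DKO against WT at each stage, P14 against WT at day 2 and day 4, and 3 interactions, which test whether a genotype's difference from WT changes between stages. The planned test depended on the unit, and the branch for normalized values was used because the table holds scaled log2 values, not raw counts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the annotation and the figures.

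The groups, the comparisons, the tests for each unit, 22 gene lists, the rule for naming genes and most alternatives were set before the data were examined. The lists cover naive, general and formative pluripotency, primitive streak and early mesoderm, neuroectoderm, primitive endoderm, trophectoderm, primordial germ cell specification, germline genes controlled by DNA methylation, DNA methylation machinery, FGF and ERK signalling, Wnt target genes, Nodal and Activin targets, the 2-cell-like state, imprinted genes, fibroblast and feeder markers, p53 targets, glycolysis and hypoxia, cholesterol synthesis, neighbours of Prdm14 on its chromosome, partners of Prdm14 and mitochondrially encoded genes. The Nodal and Activin list also holds Bmp4, Id1, Id2 and Id3, so its shifts are not those of Nodal genes alone. Each list was tested in each comparison with fry, the directional rotation test of limma, and adjusted over all 242 tests. fry asks whether the members of a list move one way on balance and does not compare them with other genes. Each list was also tested with camera with an estimated correlation, and the members past the threshold were counted both over all genes and adjusted over the list alone.

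Genes were named by a fixed rule: Prdm14; the 5 largest rises and 5 largest falls past the threshold with a mean of at least 10 in 1 of the groups and both libraries of 1 group above both of the other, leaving out pseudogenes and unnamed gene models; and up to 4 members with the smallest adjusted p of lists that passed or were marked in advance. At most about 30 genes were taken per comparison, lists in order of their p. For interactions the rule took the 3 largest of each sign. A few results that the rule selected are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

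The labels name no batch. The replicates of a group correlated at 0.973 to 0.988 across genes. The method was tested on simulated data for DKO against WT at day 4, with each gene at its mean over all 16 libraries. Changed genes were drawn from those with a mean of at least 100, so recovery of weaker genes was not measured. Of these, 91 of 100 changed 2-fold and 100 of 100 changed 4-fold were recovered. There were 15 false calls among 206, in 21450 genes. In the same simulation a raised list gave a fry p of 1.02e-08, and 0 of 20 unchanged lists fell under 0.05.

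The alternatives were other pseudocounts, filters and scalings, limma-voom on recovered reads scaled to their totals, a fit of only the groups compared, a replicate block, a 2-fold minimum, leaving out each library, camera, and lists without genes held by more than 1 list. A pseudocount of 4, scaling to the total of the named entries, a minimum mean of 50, and the general pluripotency list without Pou5f1 were added after seeing the data. DKO and P14 share the WT libraries of their day, so overlaps between them were set beside 100 simulations of unchanged groups and beside a split in which each was compared with a different WT library. In the simulations genes varied independently of each other. Leaving out a library left 1 in its group, so fewer calls are expected in those fits from the larger standard error alone.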

Results

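The transcriptomes of 16 libraries describe mouse embryonic stem cells as they leave the naive state, in WT cells, in cells labelled DKO and in cells labelled P14. Each of the 8 groups held 2 libraries with 20696359 to 32710607 recovered reads. Group values are normalized read counts given as mean ± SD with n = 2, and changes are log2 fold changes from limma with adjusted p. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples. They also name no separate clones, so a difference between labels cannot be told apart from one between cell lines.

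Component 1 of the 500 most variable genes held 55.8% of the variance and followed the stages. WT groups lay at -51.6 in 2i medium, 7.60 at day 2 and 54.2 at day 4. DKO-labelled groups lay at -55.9, -7.86 and 31.3, and P14 groups at -6.87 on day 2 and 29.1 on day 4. Both sets of modified cells thus sat below WT cells of the same day on this axis.

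**Figure D1:**
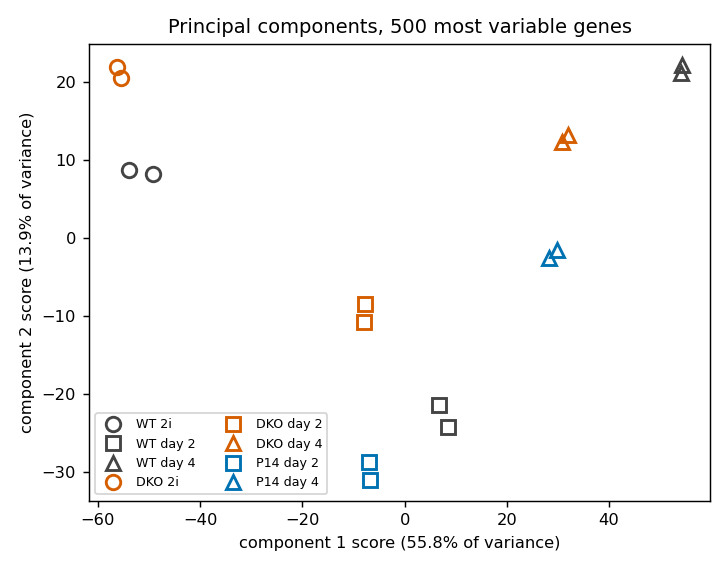
Component 1 (55.8% of variance) against component 2 (13.9%) for the 16 libraries, with colour for the label and shape for the stage. Libraries of a group lie together, and DKO and P14 libraries at day 4 lie to the left of WT day 4.

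Prdm14 encodes a zinc finger protein that protects naive pluripotency and takes part in germ cell specification. It lies on chromosome 1 at 13113457 to 13127163 (minus strand, GRCm38). In WT cells its level was 1089 ± 9.43 in 2i medium (SD, n = 2), 669 ± 61.5 at day 2 and 193 ± 37.4 at day 4. P14 cells held 10852 ± 259 at day 2 and 7534 ± 679 at day 4, which is 16.2-fold and 39.2-fold above WT (log2 4.02, adjusted p = 1.2e-11, and 5.29, adjusted p = 5.9e-13). The libraries labelled DKO did not show less Prdm14 than WT but more. They held 1803 in both 2i libraries, 1310 ± 52.7 at day 2 and 583 ± 17.0 at day 4. These are 1.65-fold (log2 0.73, adjusted p = 0.0014), 1.96-fold (0.97, adjusted p = 6.3e-05) and 3.04-fold (1.61, adjusted p = 2.4e-07) above WT. The values do not show whether DKO cells lack the gene's product or an element that controls it, so every direction below is that of libraries labelled DKO.

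**Figure D2:**
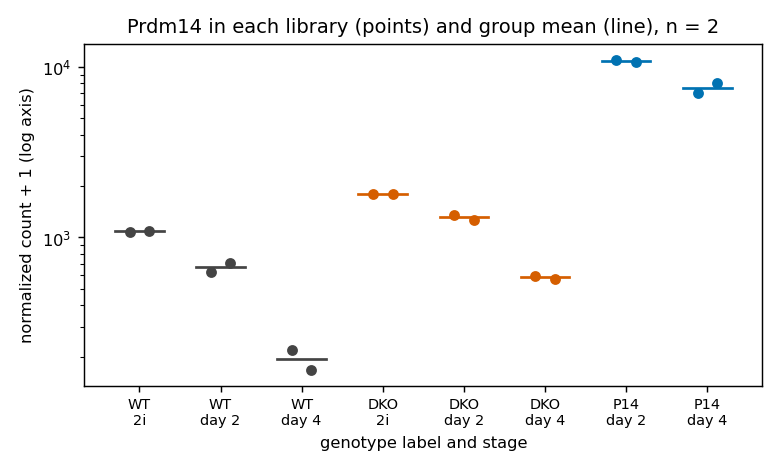
Normalized read count of Prdm14 plus 1 on a log axis for each library (points) with the group mean (line), by label and stage. DKO-labelled libraries lie above WT at every stage, and P14 libraries lie highest, at means of 10852 and 7534.

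WT cells moved from 2i medium to day 2 of induction lost much of the naive program and gained formative transcripts. Factors that hold the naive state fell, while de novo DNA methyltransferases and early postimplantation factors rose. Genes of the primitive endoderm rose in the same step. In all, 5027 of 21450 genes changed, 2718 upward and 2309 downward.

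Among 19 measured naive genes, 17 were lower and 1 was higher, and the counts adjusted over the list alone were the same (median log2 change -2.15, fry adjusted p = 4.4e-10). Nanog fell from 8442 ± 149 to 898 ± 84.8 (log2 -3.24, adjusted p = 7.0e-12), Esrrb by 7.06-fold and Tfcp2l1 by 16.3-fold. Gbx2 was the naive gene that rose (4.73-fold); a noncoding transcript overlaps it. Of 20 formative genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; fry adjusted p = 7.96e-08). Dnmt3a rose 10.2-fold to 9656 ± 147, Lef1 75.3-fold, Pou3f1 18.1-fold and Sox4 6.46-fold. The DNA methylation list had 7 genes higher and 3 lower both over all genes and adjusted over the list alone (adjusted p = 1.41e-06, but 0.0682 with an estimated correlation). Dnmt3b rose 3.18-fold and Dnmt3l 3.93-fold, while Tet2 fell (log2 -0.68).

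Of 16 primitive endoderm genes, 11 were higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 4.83e-09). Gata6, a regulator of that lineage, rose 68.1-fold from 7.84 ± 0.897 to 602 ± 78.7, Pdgfra 14.5-fold and the basement membrane genes Lamb1 and Col4a1 4.65-fold and 2.84-fold. Nodal and Activin targets divided, with 4 higher and 6 lower (4 and 6 adjusted over the list alone; adjusted p = 1.29e-06, but 0.103 with an estimated correlation). Smad7 fell 8.29-fold and Bmp4 9.08-fold, while Skil rose 3.75-fold. Cholesterol synthesis genes rose, with 11 of 15 higher and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 2.54e-06). The 5 largest rises were in Cphx2, Cphx3 and Cphx1 (at least 215-fold, 215-fold and 100.1-fold), Car4 (at least 52.2-fold) and Wt1 (126-fold). The Cphx genes are near-identical paralogs that reads cannot easily tell apart. The 5 largest falls were in Sp5 (142-fold), a Wnt target, Sh2d4b (104-fold), Evx1 (at least 33.4-fold), Trpm1 (at least 57.8-fold) and Tlx2 (at least 61.0-fold).

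Between day 2 and day 4 WT cells lost more of their pluripotency transcripts. Naive, general pluripotency and Nodal pathway genes fell together, while the formative list divided into 7 higher and 8 lower (7 and 10 adjusted over the list alone) and did not pass (fry adjusted p = 0.082). The methyltransferase genes Dnmt3a and Dnmt3l, which had risen by day 2, fell again. Neural, p53-response and imprinted transcripts rose. In this step 7072 genes changed, 3680 upward and 3392 downward. The balance depended on scaling: 2697 higher and 4997 lower with libraries centred on their median, and 4224 and 2397 with limma-voom.

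Naive genes were lower in 16 cases and higher in 1 (16 and 1 adjusted over the list alone; median -2.36, adjusted p = 9.18e-11). Nanog fell to 31.9 ± 0.853, a further 27.3-fold (adjusted p = 4.3e-14), Nr0b1 fell 38.6-fold, Fgf4 38.0-fold and Esrrb 10.8-fold. Of 16 general pluripotency genes, 13 were lower and 1 higher (14 and 2 adjusted over the list alone; adjusted p = 9.99e-10). The Nodal coreceptor gene Tdgf1 fell 53.1-fold, Nodal itself 12.1-fold and the Nodal antagonist Lefty1 25.7-fold. Nodal and Activin targets were lower in 8 of 11 cases and higher in 3 (8 and 3 adjusted over the list alone; adjusted p = 2.77e-09). In the DNA methylation list 9 genes were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 4.29e-08). Tet2 fell 7.25-fold, Tet1 5.44-fold, Dnmt3l 4.71-fold and Dnmt3a 3.96-fold.

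The neuroectoderm list had 10 of 12 genes higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 1.21e-07). Zic1 rose 11.6-fold, Cdh2 7.51-fold, the neural progenitor filament gene Nes 7.13-fold and Ncam1 6.25-fold. p53 targets were higher in 10 of 12 cases and lower in 0 (the same counts adjusted over the list alone; adjusted p = 6.59e-09), with Btg2 up 4.33-fold, Phlda3 3.76-fold and Ccng1 3.30-fold. All 12 genes of the 2-cell-like state fell, also adjusted over the list alone (median -2.74, adjusted p = 5.78e-06). The largest rises were in Lbh (at least 94.1-fold), Igfbp5 (163-fold), Tnc, Cdh11 and Car10 (at least 25.3-fold, 23.2-fold and 22.9-fold). Tdgf1 and Nr0b1 were among the 5 largest falls with Krt42 (at least 36.0-fold), Arl14epl (at least 48.5-fold) and Majin (at least 15.5-fold).

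Over the whole course from 2i medium to day 4, WT cells lost nearly all Nanog. Primitive endoderm and imprinted genes were higher at day 4 than in 2i medium. A total of 8707 genes changed, 4687 upward and 4020 downward. The split was 3697 and 5884 with libraries centred on their median, 5312 and 2793 when scaled to the total of named entries, and 5373 and 2706 with limma-voom.

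Of the naive genes 18 fell and 1 rose, also adjusted over the list alone (median -4.67, adjusted p = 1.92e-12). Nanog fell 257-fold (adjusted p = 3.7e-17). The largest rises were in Crabp2 (at least 443-fold, to 1359 ± 64.7) and Stra6 (at least 189-fold), which encode a retinoic acid binding protein and a retinol transporter, and in Meox1 (731-fold), Ptn (at least 283-fold) and Cubn (at least 250-fold). Krt42, Krt17, Nkx6-3 and Myh13 fell at least 122-fold, 77.0-fold, 71.7-fold and 63.4-fold. Primitive endoderm genes rose in 14 of 16 cases and fell in 0 (15 and 0 adjusted over the list alone; adjusted p = 3.64e-10), with Col4a2 up 20.8-fold and Col4a1 17.0-fold. Imprinted genes were higher in 14 of 18 cases and lower in 1 (the same counts adjusted over the list alone; adjusted p = 2.82e-08). Igf2 rose 188-fold to 8354 ± 695, though an unnamed gene model overlaps it, and Peg10 rose 42.4-fold, Peg3 10.7-fold and Mest 8.94-fold. Lin28a rose 7.30-fold, 1 of 2 rises beside 11 falls in the general pluripotency list (3 and 11 adjusted over the list alone; adjusted p = 1.04e-08).

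In 2i medium, before induction, DKO-labelled cells already differed from WT. Hoxa9 and Hoxa11, low in WT cells, were abundant, and p53 targets were higher. Naive genes did not move as a list. De novo methylation genes and transcripts of the rare 2-cell-like state were lower. In all 1859 genes changed, 685 upward and 1174 downward. Without 1 library the count was 1031 (WT 2i replicate 1), 1073 (WT 2i replicate 2), 877 (DKO 2i replicate 1) or 949 (DKO 2i replicate 2).

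Hoxa9 stood at 535 ± 20.7 in DKO-labelled cells and 11.4 ± 12.7 in WT cells (log2 5.98, adjusted p = 2.1e-05). Hoxa11 and its overlapping antisense transcript Hoxa11os were 62.2-fold and 76.0-fold higher, Mir196b, within the Hoxa9 locus, at least 13.7-fold and Heph, a copper oxidase gene, 25.5-fold. Large falls were in Crxos (at least 23.6-fold), Liph (34.9-fold), the imprinted gene Phlda2 (17.6-fold) and Rtp2 (at least 9.68-fold). The calls of 2 of these were lost in some fits, though fewer calls are expected where 1 library is left in a group. Crxos was lost without DKO 2i replicate 1 (log2 -3.98). Rtp2 was lost without that library (-3.41) or WT 2i replicate 2 (-3.81), and also with a pseudocount of 0.1.

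p53 targets were higher in 9 of 12 cases and lower in 0, also adjusted over the list alone (median 0.69, adjusted p = 5.7e-08), with Perp up 3.77-fold, Phlda3 2.52-fold and Ccng1 2.41-fold. Naive genes had 3 higher and 1 lower of 19, also adjusted over the list alone; their median was -0.06 and mean -0.05 while fry pointed up without passing (adjusted p = 0.148). Dnmt3l was 8.79-fold lower (61.4 ± 15.1 against 540 ± 14.4), Dnmt3b 2.13-fold and Dnmt3a 1.75-fold. The DNA methylation list had 4 lower and 0 higher (5 and 1 adjusted over the list alone; adjusted p = 6.68e-05, but 0.0796 with an estimated correlation). The 2-cell-like list had 7 of 12 lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 5.91e-05), with Zscan4f 4.45-fold and Zscan4c 3.44-fold lower. General pluripotency had 6 lower and 1 higher of 16 (6 and 2 adjusted over the list alone; adjusted p = 2.94e-05), with Utf1 4.17-fold and Dppa2 2.27-fold lower. Of 10 measured neighbours of Prdm14 on its chromosome, 2 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.000114, but 0.0796 with an estimated correlation). They were Sulf1 (1.68-fold) and Msc (4.56-fold), the latter overlapped by an unnamed gene model.

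By day 2 the DKO-labelled cells held more naive transcripts than WT cells, although in a comparison added after the results were seen 14 of 19 naive genes were lower and 2 higher than in DKO-labelled cells in 2i medium (median -1.03, fry adjusted p = 6.27e-08). Nanog, Esrrb, Klf4 and Tbx3 were higher and formative genes were lower than in WT cells. Hoxa11 was again higher and the imprinted growth inhibitor Cdkn1c was strongly reduced. A total of 2707 genes changed, 1283 upward and 1424 downward. Other scalings gave 1452 and 802 (total of named entries), 1688 and 1037 (library size without mitochondrial and top 10 genes) and 1559 and 892 (limma-voom). Without 1 library the count was 1336 (WT day 2 replicate 1), 1633 (WT day 2 replicate 2), 1484 (DKO day 2 replicate 1) or 1494 (DKO day 2 replicate 2).

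Naive genes were higher in 11 cases and lower in 3 (12 and 3 adjusted over the list alone; median 0.84, adjusted p = 2.82e-08). Nanog stood at 4536 ± 341 against 898 ± 84.8 (5.05-fold, adjusted p = 6.8e-10), with Klf4 up 5.75-fold, Esrrb 4.69-fold and Tbx3 4.10-fold. Formative genes were lower in 9 of 20 cases and higher in 1 (10 and 2 adjusted over the list alone; adjusted p = 4.19e-05), with Pou3f1 down 6.21-fold, Dnmt3b 3.06-fold and Lef1 by log2 -1.81. Nodal and Activin targets were higher in 4 of 11 cases and lower in 0 (6 and 0 adjusted over the list alone; adjusted p = 2.3e-06), including Smad7 (4.36-fold) and Id3 (4.84-fold). The call of Nodal itself was lost when any library of these groups was left out (log2 0.57 to 0.69). That of Id1 was lost without WT day 2 replicate 1 (1.22) or 2 (1.00) or DKO day 2 replicate 2 (0.92). Genes of primordial germ cell specification were higher in 7 of 13 cases and lower in 0 (7 and 2 adjusted over the list alone; adjusted p = 7.95e-06), including Prdm1 (3.09-fold) and Kit (2.24-fold). Neighbours of Prdm14 were higher in 5 of 10 cases and lower in 1 (7 and 1 adjusted over the list alone; adjusted p = 1.12e-06), with Msc up 15.0-fold and Prex2 1.75-fold. These are not the nearest genes. Ncoa2, Slco5a1 and Tram1 (11942, 120807 and 437535 bases away) did not pass (limma adjusted p = 0.056, 0.13 and 0.75). Sulf1 (252265 bases) was lower (log2 -0.31) and Lactb2 (496167 bases) higher (0.60). At day 4 Ncoa2 (-0.41) and Tram1 (-0.45) were lower, and Slco5a1, Sulf1 and Lactb2 did not pass. Primitive endoderm genes had 2 higher and 1 lower, also adjusted over the list alone, and did not pass (adjusted p = 0.124).

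Cdkn1c, on chromosome 7 at 143458339 to 143461050, stood at 194 ± 47.6 against 6026 ± 778 in WT cells (31.2-fold lower, adjusted p = 5.4e-10). An unnamed gene model on the other strand overlaps it. The other large falls were in Tmem151a (at least 12.1-fold), Phlda2 (27.7-fold), Hoxb1 (18.2-fold) and Pld4 (17.4-fold). The call for Hoxb1 was lost with a pseudocount of 0.1. The large rises were in Hoxa11os (43.2-fold), Hoxc10 (at least 24.2-fold), Hoxa11 (32.3-fold), Vax2os (28.7-fold) and Hoxc6 (at least 9.73-fold). Imprinted genes went both ways, with 4 higher and 7 lower (6 and 8 adjusted over the list alone; adjusted p = 0.000217, but 0.353 with an estimated correlation).

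At day 4 the gap in the naive program between DKO-labelled and WT cells was wide. Nanog and Esrrb, low in WT cells, were higher, and genes of the Nodal pathway and of germ cell specification were also higher. Cdkn1c stayed low. A total of 2950 genes changed, 1491 upward and 1459 downward. With limma-voom the split was 1001 and 1904, and without WT day 4 replicate 2 it was 1011 and 648. The count was 1786 without WT day 4 replicate 1, 1659 without replicate 2 and 1828 without DKO day 4 replicate 1.

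Naive genes were higher in 14 cases and lower in 0 (15 and 1 adjusted over the list alone; median 2.14, adjusted p = 9.27e-11). Nanog stood at 995 ± 8.57 against 31.9 ± 0.853 (30.3-fold, adjusted p = 5.4e-14), Esrrb was 25.8-fold, Nr0b1 25.3-fold and Tbx3 11.9-fold higher. Nodal and Activin targets were higher in 8 cases and lower in 1 (8 and 2 adjusted over the list alone; adjusted p = 7.95e-09), with Tdgf1 and Lefty1 each 10.7-fold and Nodal 5.48-fold higher. General pluripotency was higher in 10 cases and lower in 2 (11 and 2 adjusted over the list alone; adjusted p = 6.9e-08), but Cdh1, the epithelial cadherin, was 4.35-fold lower. Formative genes divided into 7 higher and 8 lower (8 and 8 adjusted over the list alone), with a median of -0.20, a mean of 0.38 and an upward fry that did not pass (adjusted p = 0.0547). With a replicate block this list passed (fry adjusted p = 0.0418). In the DNA methylation list 4 were higher and 2 lower (5 and 2 adjusted over the list alone; adjusted p = 5.06e-06), including Tet2 (3.71-fold), Tet1 (2.77-fold) and Dnmt3a (2.56-fold). Genes of primordial germ cell specification were higher in 8 cases and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 3.84e-07), including Dppa5a (5.08-fold).

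p53 targets, higher in 2i medium, were now lower in 4 cases and higher in 0 (5 and 1 adjusted over the list alone; adjusted p = 1.55e-05), with Ccng1 1.98-fold lower. Imprinted genes were lower in 11 cases and higher in 1 (12 and 3 adjusted over the list alone; adjusted p = 1.63e-05, but 0.0546 with an estimated correlation). The largest rises were in Hoxa11 and Hoxa11os (at least 43.0-fold and 29.4-fold), Hoxa10 (98.8-fold), Hoxa9 (78.8-fold) and Inhbb (63.0-fold), which encodes an activin subunit. The largest falls were in Crabp2 (34.9-fold), Cdkn1c (29.2-fold), Slc22a18 and Elfn2 (at least 8.80-fold each) and Il23a. Il23a varied from 21.6 to 5204 between DKO day 4 libraries and from 11659 to 25460 between WT libraries. Its call was lost without WT day 4 replicate 1 (log2 -6.21), WT day 4 replicate 2 (-5.09) or DKO day 4 replicate 1 (-1.73), and in a fit of only the groups compared.

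**Figure D3:**
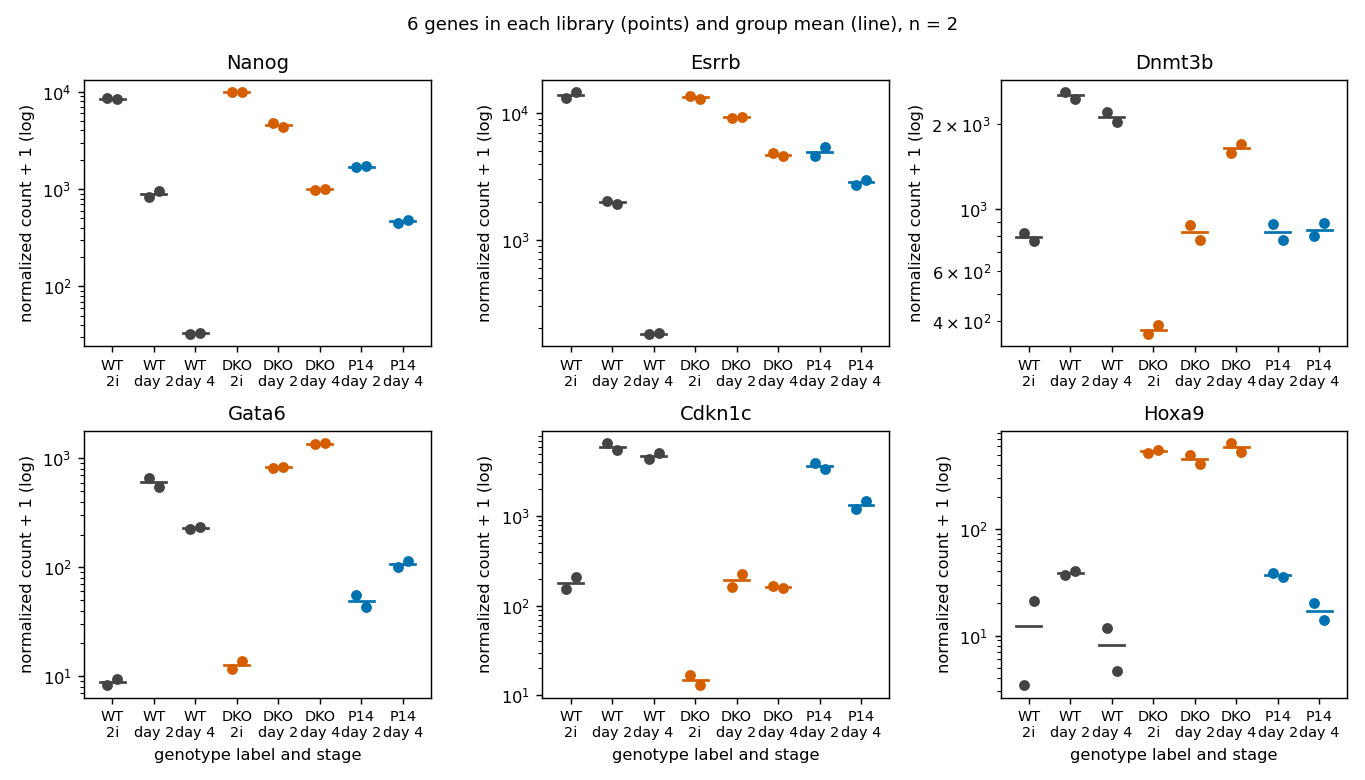
Normalized read counts of Nanog, Esrrb, Dnmt3b, Gata6, Cdkn1c and Hoxa9 in each library by label and stage. Nanog and Esrrb stay above WT in DKO and P14 cells at day 2 and day 4, Hoxa9 is high and Cdkn1c low in DKO-labelled cells at each stage, and Gata6 is low in P14 cells.

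P14 cells at day 2, with Prdm14 far above WT, held less of the primitive endoderm transcripts that WT cells had gained. Meg3, Rian and Mirg, noncoding genes of the imprinted Dlk1-Dio3 region, were also low. Naive genes were modestly higher and DNA methyltransferases lower. A total of 1797 genes changed, 791 upward and 1006 downward. The count was 858 without WT day 2 replicate 1, 976 without WT day 2 replicate 2 and 1046 without P14 day 2 replicate 1, and 796 when only the groups compared were fitted.

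Of 16 primitive endoderm genes, 11 were lower and 1 higher, also adjusted over the list alone (median -1.47, adjusted p = 1.05e-08). Pdgfra stood at 3.67 ± 1.94 against 268 ± 41.8 (59.9-fold lower, adjusted p = 1.6e-08), Gata6 was 12.2-fold, Lama1 8.40-fold and Gata4 7.96-fold lower. Foxa2, a regulator of endoderm, was at least 10.9-fold lower and Wnt8a at least 26.5-fold lower. Imprinted genes were lower in 7 of 18 cases and higher in 1 (9 and 2 adjusted over the list alone; adjusted p = 7.01e-06, but 0.0528 with an estimated correlation), led by Meg3 (36.0-fold), Mirg (25.4-fold) and Rian (log2 -4.26). Naive genes were higher in 10 cases and lower in 1 (13 and 1 adjusted over the list alone; median 0.92, adjusted p = 3.6e-07), with Tdh up 3.51-fold and Esrrb 2.51-fold. The DNA methylation list had 4 lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 4.9e-06), with Dnmt3l down 7.60-fold and Dnmt3b 3.04-fold. Formative genes were lower in 9 cases and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 7.01e-06), with Sox11 down 4.66-fold and Sox4 4.25-fold.

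Nodal and Activin targets were lower in 5 cases and higher in 1 (6 and 1 adjusted over the list alone; adjusted p = 6.68e-05, but 0.0777 with an estimated correlation and 0.136 without WT day 2 replicate 1). Lefty1 was 3.58-fold lower and Id3 6.48-fold higher. Besides Prdm14, the largest rises were in weakly expressed genes: Olfr640 (at least 8.17-fold), Vamp5 (at least 7.48-fold), Nkain4 (at least 5.56-fold) and Tnfaip2 (13.0-fold, to 76.4 ± 0.926). Without WT day 2 replicate 1 or replicate 2 the calls of Vamp5 (log2 4.42 in each case) and Olfr640 (3.70 in each case) were lost, and that of Vamp5 also without P14 day 2 replicate 1 (3.77). limma-voom ended both calls, and a pseudocount of 0.1, scaling to the total of named entries or a fit of only the groups compared ended that of Olfr640. Ccdc194 was the other of the largest falls (at least 23.2-fold).

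At day 4 P14 cells held more naive transcripts than WT cells. They held less of the primitive endoderm and neural transcripts that WT cells had gained. Imprinted transcripts were also lower than in WT cells, and of these Mirg and Rian had already been low at day 2. Cholesterol synthesis genes were slightly but widely lower. Germline genes normally silenced by DNA methylation were higher. A total of 3471 genes changed, 1594 upward and 1877 downward, against 1129 and 2043 with limma-voom. Without 1 library the count was 2274 (WT day 4 replicate 1), 2140 (WT day 4 replicate 2), 2150 (P14 day 4 replicate 1) or 2310 (P14 day 4 replicate 2).

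Naive genes were higher in 16 cases and lower in 1 (17 and 1 adjusted over the list alone; median 1.96, adjusted p = 4.19e-10). Esrrb was 15.6-fold, Nanog 14.2-fold (466 ± 18.8 against 31.9 ± 0.853, adjusted p = 7.8e-13) and Nr0b1 13.0-fold higher. Primitive endoderm genes were lower in 12 cases and higher in 1 (13 and 1 adjusted over the list alone; median -2.45, adjusted p = 2.7e-09), with Cubn 87.2-fold, Dab2 20.6-fold and Lama1 15.5-fold lower. Imprinted genes were lower in 13 cases and higher in 1 (15 and 2 adjusted over the list alone; adjusted p = 1.61e-07), with Mirg 21.6-fold, Rian 17.2-fold and Peg3 5.57-fold lower. Neuroectoderm genes were lower in 7 of 12 cases and higher in 0, also adjusted over the list alone (adjusted p = 1.88e-06), with Zic1 7.55-fold, Cdh2 6.74-fold and Sox1 4.18-fold lower. Cholesterol synthesis genes were lower in 13 of 15 cases and higher in 0 (15 and 0 adjusted over the list alone; median -0.74, adjusted p = 8.23e-07), such as Hmgcs1 (1.86-fold) and Msmo1 (1.84-fold).

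Germline genes controlled by DNA methylation were higher in 11 of 18 cases and lower in 0 (12 and 0 adjusted over the list alone; adjusted p = 1.51e-05). Formative genes divided into 5 higher and 11 lower (6 and 11 adjusted over the list alone; adjusted p = 5.12e-06, but 0.108 with an estimated correlation). For Nodal and Activin targets, with 4 higher and 4 lower (4 and 6 adjusted over the list alone), the median of -0.58 and mean of -0.41 ran against an upward fry (adjusted p = 0.0103, but 0.915 with an estimated correlation), which reversed without P14 day 4 replicate 1 (0.0268). The other large rises were in the peptide transporter gene Slc15a1 (50.8-fold), Pvalb (33.5-fold), Oas2 (at least 16.5-fold) and Ephx2 (20.2-fold). The call for Pvalb was lost with a pseudocount of 0.1. Btbd17 was 49.9-fold lower, and Wnt8a, Aldh1a7 and Pcdh18 were at least 110-fold, 30.4-fold and 26.3-fold lower.

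**Figure D4:**
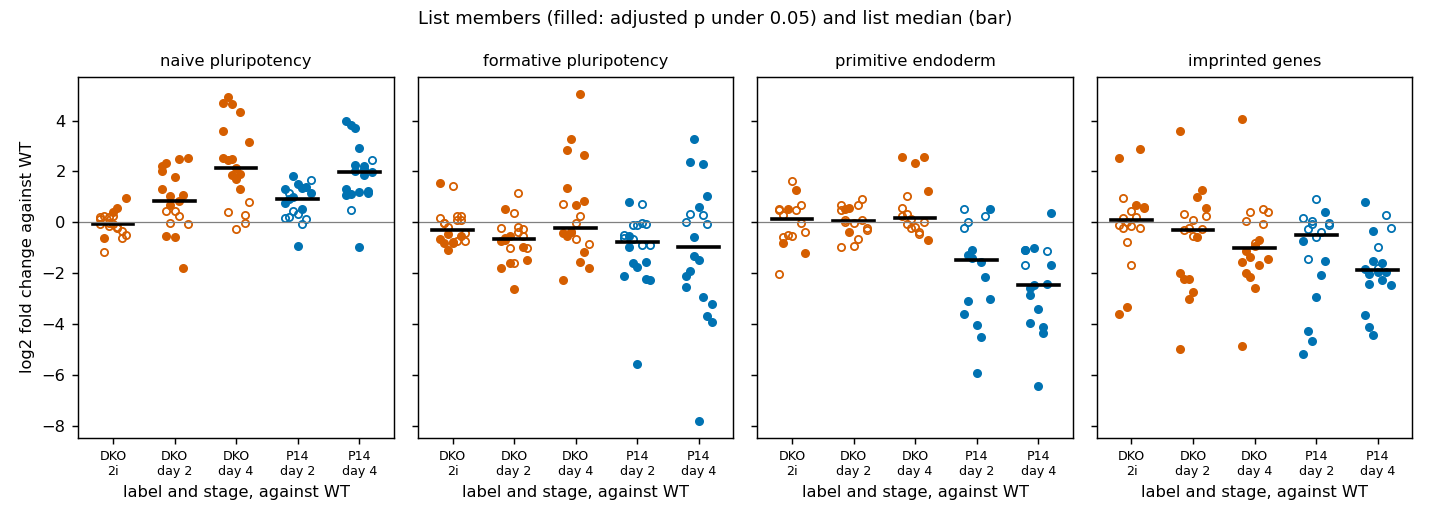
Log2 fold change against WT of the same stage for each member (points, filled where adjusted p is under 0.05) of the naive, formative, primitive endoderm and imprinted lists, with the median as a bar. Naive medians at day 4 are 2.14 in DKO-labelled and 1.96 in P14 cells, and primitive endoderm genes are low in P14 cells only.

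DKO-labelled and P14 cells shared many of their differences from WT, although they also share the WT libraries. At day 2, 303 genes were higher in both and 277 lower in both, and 115 moved in opposite directions. At day 4 these counts were 730, 635 and 103. Independence would give 47.3 and 66.8 at day 2 and 110.8 and 127.7 at day 4. With a different WT library for each, 132 or 138 genes were higher in both and 111 or 94 lower in both at day 2, and 434 or 439 and 294 or 307 at day 4. For these splits independence would give 14.6 higher and 17.3 or 15.5 lower at day 2. At day 4 it would give 48.0 or 49.0 higher and 38.1 or 41.3 lower. The log2 changes of the splits correlated at 0.105 or 0.111 on day 2 and 0.322 or 0.307 on day 4. Across genes, the log2 changes correlated at 0.35 on day 2 and 0.54 on day 4, against 0.50 in both simulations of a shared control; genes are not independent replicates. Their covariance was above that of the simulation by 0.0853 at day 2 and 0.277 at day 4.

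On balance, genes of the WT time course were displaced toward their starting level in both. Of the 2718 genes that rose by day 2 in WT cells, 603 were lower and 123 higher in DKO-labelled cells at day 2, and 407 and 56 in P14 cells. Of the 2309 that fell, 617 were higher and 117 lower in DKO-labelled cells, and 419 and 97 in P14 cells. For the 4687 genes that rose by day 4, 938 were lower and 98 higher at day 4 in DKO-labelled cells, and 1217 and 157 in P14 cells. For the 4020 that fell by day 4, 1085 were higher and 112 lower in DKO-labelled cells, and 1055 and 161 in P14 cells. These genes were chosen with the WT libraries of the same day, which alone would move them toward the starting level. In simulated unchanged groups the mean medians were -0.05 (rising) and 0.05 (falling) at day 2 and -0.04 and 0.03 at day 4. The observed medians were -0.28 and 0.29 at day 2 and -0.42 and 0.29 at day 4 in DKO-labelled cells, and -0.22 and 0.25, then -0.36 and 0.27, in P14 cells. With genes chosen from WT day 4 against 2i, the day 2 displacement was smaller. Of the rising genes 586 were then lower and 278 higher in DKO-labelled cells at day 2 (median -0.09), and 428 and 146 in P14 cells (median -0.07). Of the falling genes 604 were higher and 333 lower in DKO-labelled cells (median 0.05), and 375 and 197 in P14 cells (median 0.07). The primitive endoderm list did not show this displacement in DKO-labelled cells at day 4. From 2i medium to day 4, 16 of 16 genes rose there (median 4.02), in a comparison added after the results were seen. In WT cells 14 of 16 rose (median 3.62).

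Wnt targets had 6 of 15 lower and 1 higher in DKO-labelled cells at day 2, also adjusted over the list alone (adjusted p = 0.00315, but 0.179 with an estimated correlation). FGF and ERK signalling genes had 9 of 20 higher and 3 lower in DKO-labelled cells at day 4, also adjusted over the list alone (adjusted p = 0.000287, but 0.0771 with an estimated correlation). Primitive streak genes had 3 of 12 lower and 0 higher in P14 cells at day 2 (4 and 0 adjusted over the list alone; adjusted p = 0.000243, but 0.0874 with an estimated correlation). Fibroblast markers had 4 of 7 lower and 0 higher in P14 cells at day 4 (6 and 0 adjusted over the list alone; adjusted p = 2.14e-06). In WT cells from day 2 to day 4, 4 of the 7 were higher and 0 lower, also adjusted over the list alone (median 1.64, adjusted p = 2.85e-06, but 0.0546 with an estimated correlation). In comparisons of that step added after the results were seen, P14 cells had 0 higher and 0 lower. DKO-labelled cells had 4 higher and 0 lower (median 1.13, fry adjusted p = 1.88e-05). Such counts do not by themselves test whether the labels differ in this step. Trophectoderm genes had 4 of 11 lower and 1 higher in P14 cells at day 4 (4 and 2 adjusted over the list alone; adjusted p = 0.00267, but 0.378 with an estimated correlation). Partners of Prdm14 had 3 of 10 higher and 0 lower in P14 cells at day 2, also adjusted over the list alone (adjusted p = 0.000635, but 0.0546 with an estimated correlation). Glycolysis genes had 10 of 16 lower and 2 higher over the WT course (10 and 3 adjusted over the list alone; adjusted p = 4.28e-06, but 0.119 with an estimated correlation). Mitochondrially encoded genes passed fry in none of the 11 comparisons; in P14 cells at day 2, 0 of 13 changed over all genes, and 6 were higher and 1 lower adjusted over the list alone (adjusted p = 0.332). In DKO-labelled cells at day 4, 1 was lower and 0 higher than in WT (4 and 0 adjusted over the list alone; median -0.58, adjusted p = 0.0826). In comparisons added after the results were seen, 10 of 13 were lower in DKO-labelled cells at day 4 than in 2i medium (fry adjusted p = 0.00524), and 6 were higher in P14 than in DKO-labelled cells at day 4 (fry adjusted p = 0.0229).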

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

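Of the tests of explanations below, only that of exchanged labels was written before the results were seen; all others were chosen afterwards.

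Prdm14 was higher in the libraries labelled DKO than in WT at every stage, although the series describes a knockout. Scaling is an unlikely source, since the lowest log2 change over 3 stages, the deposited scaling and 6 others was 0.71. Exchanged WT and DKO labels would place P14 cells, if made from unedited cells, near the DKO-labelled level. Over genes that differ at least 4-fold at all 3 stages, the median position of P14 cells was instead 0.2002. The scale ran from WT (0) to DKO (1), with 0.133 at day 2 and 0.325 at day 4. Several of these genes share a locus, so they are not independent. A delayed exit from the naive state alone would leave 2i medium unchanged, where the log2 change was already 0.73 (SE 0.12). What the DKO label removed stays open, as does whether the measured transcript makes a working protein.

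Naive genes were higher at day 4 in both DKO-labelled and P14 cells. Gene-by-gene chance values of the shared WT libraries are an unlikely source: the smaller of the medians was 1.96, and the highest of 100 simulated medians was 0.0997. The simulated genes varied independently, so WT libraries in which naive genes moved together by chance are not excluded. Fewer pluripotent cells in the WT day 4 libraries stay possible: the median change of the general pluripotency list in WT cells exceeded that of the naive list by 3.98, but its members ran from -7.48 (Tdgf1) to 2.87 (Lin28a). The level of Prdm14 alone would put P14 cells above DKO-labelled cells if naive genes rose steadily with it. The median difference of naive genes, P14 minus DKO, was -0.50 (fry adjusted p = 3.66e-07). This cannot decide about a response that levels off, nor if the transcript of DKO-labelled cells makes no working protein. Whether the shared change came from Prdm14 itself, a slower course of induction, the mix of cells or differences between the cell lines stays open.

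The difference from WT changed between stages, as tested by interaction terms, for 801 genes in DKO-labelled cells from 2i medium to day 2, 2093 from 2i medium to day 4, and 1165 in P14 cells from day 2 to day 4. The first count was 453 without WT day 2 replicate 1, 501 without DKO 2i replicate 1, and 471 or 467 without DKO day 2 replicate 1 or 2. The last was 720 or 726 without WT day 2 replicate 1 or 2, 695 without WT day 4 replicate 2, 744 without P14 day 4 replicate 1 and 1944 without P14 day 2 replicate 2. Splits were 519 higher and 282 lower for the first (447 and 143 scaled to the total of named entries, 498 and 122 with limma-voom), 1246 and 847 for the second (746 and 852 with limma-voom) and 537 and 628 for the last (664 and 486 with libraries centred on their median).

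The interaction term of Prdm14 was 0.88 in DKO-labelled cells from 2i medium to day 4 (limma adjusted p = 0.0033) and 1.27 in P14 cells from day 2 to day 4 (limma adjusted p = 0.00035). In DKO-labelled cells from 2i medium to day 2 the largest terms were those of Acp7 (5.39), Tmem132d (5.30), Crxos (5.26), Ntrk2 (-5.99), Bhlhe41 (-5.68) and Crabp2 (-4.75). The call of Acp7 was lost without WT 2i replicate 2 (4.61), WT day 2 replicate 1 (4.63), DKO 2i replicate 2 (4.20), DKO day 2 replicate 1 (5.68) or replicate 2 (5.10). That of Crxos was lost without WT 2i replicate 1 (5.09) or 2 (5.43), WT day 2 replicate 1 (5.90) or 2 (4.62), DKO 2i replicate 1 (3.90), or DKO day 2 replicate 1 (5.21) or 2 (5.31). From 2i medium to day 4 they were those of Crxos (6.44), Krt42 (6.16), Majin (6.14), Sprr2a1 (-8.16), Sprr2a2 (-7.98) and Crabp2 (-7.06).

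In P14 cells from day 2 to day 4 large interaction terms were those of Adm (4.60), Grap2 (4.35), D6Ertd527e (4.24), Pcdh18 (-6.45) and Sparcl1 (-6.23). The call of Adm was lost without WT day 2 replicate 1 (4.01), WT day 4 replicate 1 (4.42) or 2 (4.79), P14 day 2 replicate 1 (3.74), or P14 day 4 replicate 1 (4.52) or 2 (4.69). That of Grap2 was lost without WT day 2 replicate 1 (4.44) or 2 (4.27), WT day 4 replicate 2 (4.06) or P14 day 4 replicate 2 (3.98). That of D6Ertd527e was lost without WT day 2 replicate 2 (3.64), WT day 4 replicate 1 (4.33) or 2 (4.16) or P14 day 4 replicate 2 (3.87). Other fits also ended calls: a pseudocount of 0.1 those of Acp7, Crxos to day 2 and Adm, limma-voom those of Acp7, Adm and D6Ertd527e, a fit of only the groups compared that of D6Ertd527e, and centring on the median or scaling to the total of named entries that of Crxos to day 2. Several of these genes were at 0 in a group, so their terms depend on the pseudocount and are no bound. A median of 8.94% of reads lay on entries without a symbol, a signal that was not tested here.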

How the results depend on the processing

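Across the alternatives, 5234 of 5345 values of named genes kept their call, 109 were weaker, 2 stronger and 0 reversed, and of 2453 list values 2183 stayed the same, 216 were weaker, 41 stronger and 13 reversed. Fits with edgeR and DESeq2 are not reported here, because the design kept them for a file of counts and the deposited unit is log2; limma-voom, scaled to library totals, was the fit on recovered reads. Named genes were mostly picked for large changes or small adjusted p in these data, so most would keep their call for that reason. Values of named genes that a filter removed were not counted. A minimum mean of 50 covered 227 of 267 such values, and the other stricter filter covered 230. With 2 libraries per group, a library left alone in its group was assumed to vary like the others. In 242 list tests, 104 calls were lost in camera with an estimated correlation and 45 with a preset correlation, so many list results rest on treating the members as fry does. Overlapping genes limit single values, because the strand setting is not given in the sources used here.

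Counts of changed genes depended on a fold minimum and, in most fits, fell when 1 library was left out. Fewer calls are expected there, because the group then held 1 library. With a 2-fold minimum they were 2643 (WT day 2 against 2i), 3688 (WT day 4 against day 2), 5168 (WT day 4 against 2i), 917, 1116 and 1247 (DKO at 2i, day 2, day 4), 769 and 1808 (P14 at day 2, day 4), and 505, 1349 and 754 (interactions DKO to day 2, DKO to day 4, P14). Without 1 library, in the same order, they ran from 3442 to 3793, 4945 to 5282, 6876 to 7310, 877 to 1073, 1336 to 1633, 1659 to 2243, 858 to 2655, 2140 to 2310, 453 to 556, 1460 to 1741 and 695 to 1944. The highest values for P14 day 2 and the P14 interaction, 2655 and 1944, were those without P14 day 2 replicate 2, and without replicate 1 P14 day 2 gave 1046. The P14 interaction gave 762 with limma-voom and 776 when only the groups compared were fitted, and P14 day 2 then gave 796; the cause was not tested. Scaling moved the median log2 change of all genes by -0.18 in WT day 4 against day 2 and -0.21 in WT day 4 against 2i with libraries centred on their median, and by 0.10, 0.16 and 0.11 in these and in DKO day 2 when scaled to the total of named entries.

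Replicate differences showed no common pairing of the libraries by replicate number, but a partial pairing is not excluded. Across 28 pairs of groups, these differences correlated across genes at -0.24 to 0.26 (median 0.0054, over 0.1 in 3 pairs, under -0.1 in 4). The highest value was that of WT with DKO at day 4, and the same labels gave 0.079 in 2i medium and -0.079 at day 2. In every group replicate 2 had more recovered reads than replicate 1, such as 31392913 against 21218138 in WT 2i and 21025261 against 20696359 in P14 day 2. The cause was not tested. With a replicate block the counts, in the same order, were 5069, 7100, 8738, 1825, 2686, 2985, 1845, 3430, 785, 2074 and 1147. The block ended no call of a named gene and added those of Nodal and Activin targets in DKO 2i (0.0445), glycolysis in DKO day 2 (0.0226) and formative genes in DKO day 4 (0.0418).

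Genes shared by DKO and P14 at day 2 were, in the order adjusted p under 0.01, 2-fold minimum, and a different WT library for each (either way round), 137, 86, 132 and 138 higher and 120, 94, 111 and 94 lower. At day 4 they were 442, 341, 434 and 439 higher and 324, 254, 294 and 307 lower. With time-course genes taken from WT day 4 against 2i, the share of rising genes lower at day 2 moved from 22.2% to 12.5% in DKO and from 15.0% to 9.13% in P14, and that of falling genes higher from 26.7% to 15.0% and from 18.1% to 9.33%. Component 1 held 34.9% of the variance over all genes, against 55.8%.

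Some lists changed direction. In camera, with the preset and then the estimated correlation, they were FGF and ERK signalling in WT day 4 against day 2 (0.964, 0.974), general pluripotency in DKO day 2 (0.964, 0.970) and neighbours of Prdm14 in DKO day 4 (0.988, 0.988). Without genes held by more than 1 list they were primitive streak in WT day 2 against 2i (0.0934) and WT day 4 against 2i (0.000139), FGF and ERK signalling in WT day 4 against day 2 (0.00998), germ cell specification in DKO 2i (0.221), DNA methylation in DKO day 2 (0.773) and Nodal and Activin targets in P14 day 4 (0.000133). The last also reversed without P14 day 4 replicate 1 (0.0268), and kept its direction without WT day 4 replicate 1 (0.00210) or without WT day 4 replicate 2 (0.029).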

Other observations

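The formative list divided at day 4, with 7 genes higher and 8 lower than WT in DKO-labelled cells and 5 higher and 11 lower in P14 cells. Among those higher in both, chosen after their values were seen, Fgf5 stood at 59.8 in DKO-labelled, 7.68 in P14 and 1.08 in WT cells, and Otx2 at 64.0, 63.8 and 6.75. In the same cells Sox3 was lower, by log2 -1.80 in DKO-labelled and -3.90 in P14 cells, as was Cd24a (-2.25 and -2.55). Gata6 separated the labels: 1368 in DKO-labelled, 229 in WT and 106 in P14 cells. Compared directly with DKO-labelled cells, a comparison added after the results were seen, P14 cells had 12 primitive endoderm genes lower and 1 higher (median -3.25, limma fry adjusted p = 8.99e-10).

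A set of genes differed at least 4-fold between DKO-labelled and WT cells at all 3 stages: 19 genes, of which 14 were higher. Several share a locus and are not independent. These include Hoxa6, Hoxa9, Hoxa10, Hoxa11, Hoxa11os and Mir196b, Hoxc9 with Hoxc10, and Cdkn1c with the overlapping Gm44732. Whether others, such as Phlda2 and Slc22a18, share a locus with Cdkn1c was not examined, so further members may be dependent. All 19 were chosen after their values were seen. Plagl1, an imprinted gene, stood at 3813, 722 and 1190 in DKO-labelled cells against 654, 58.9 and 71.5 in WT cells at 2i medium, day 2 and day 4. On a scale from WT (0) to DKO (1), the median position of these genes in P14 cells was 0.133 at day 2 and 0.325 at day 4, where single genes ran as high as 0.852 (Ltb).

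The tests of the next pattern were chosen after the results were seen.

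Pou5f1, a core pluripotency gene, stood at only 12.1 in WT cells in 2i medium. A locus without transcripts is an unlikely cause, since Gm19553, which has 64.2% of its exon bases within Pou5f1 exons, stood at 8639. Loss of reads that overlap both genes would touch a small part of Pou5f1 by GENCODE M21, where 14.1% of its exon bases lie within Gm19553 exons. The annotation and overlap rule used for counting are not given, so this share cannot exclude such a loss. In other loci, 58 antisense genes held a median log2 read density of 0.73 over their host (quartiles -0.283 to 1.09). Of 21455 named entries 21450 passed the filter, so antisense genes that lost all reads would be absent and this density cannot decide. Whether reads that also match pseudogenes were dropped was not tested and stays open, so the Pou5f1 value was not read as a level.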
